A study of Mus musculus with 6 samples.

How the data were processed

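RNA levels were measured on Affymetrix arrays in 6 samples of sorted mouse leukemia cells, 3 Ppara+/+ and 3 Ppara-/-, and the groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted from GFP-positive cells and labelled with biotin. The deposited values are log2 signals, 1 per probe set and array, and the submitters' processing notes name RMA (robust multi-array average, which corrects background, normalizes by quantiles and summarises probes) and limma, with no version or order. Quantile normalization gives arrays near-equal distributions, so a shift of most genes in 1 direction would be removed by it. Other settings, the annotation and the genome build are not given in the sources used here. The probe set identifiers have another form than those of the array model that the design text names, so the model is uncertain.

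The value table had 72688 rows, of which 6732 were control rows, 5222 of them negative controls. A platform annotation table paired 31219 of the other rows with 1 gene, 1531 with several, and left 33206 unnamed here. A symbol repeated for 1 probe set was counted once, and older symbols were updated through the gene ID with the RefSeq gene table of mouse assembly GRCm38.p6, which was used for names and for which genes neighbour each other. Each of the 30746 genes was tested through its probe set with the highest mean over the 6 arrays, and 364 genes had more than 1. No filter on dim probe sets was set, because the table has no detection calls. The 95th percentile of the negative controls was 7.91 to 8.23, and 11.3% to 14.2% of the named genes lay above it.

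Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Every adjusted p of a gene is from this fit unless another is named. The SE is the moderated one. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 32 lists with at least 5 measured genes. The lists held 1045 different genes, of which 926 were measured. They covered lipid and energy metabolism, the MLL-AF9 programme, stem cells, myeloid differentiation, antigen presentation, interferon and inflammation, immune regulation, cell cycle and stress, together with markers of other marrow cells, genes of handling stress and sex-linked genes. Camera was repeated with an estimated correlation, which is wider where genes of a list vary together, and fry asked whether a list's genes move 1 way on balance, without comparison to other genes. The repeat of camera can also raise p where the estimate equals the preset. A lost call alone therefore does not show that genes vary together. Each array's mean over a list was also compared by an exact two-sided permutation test, which cannot go below 0.1 with 3 arrays against 3. The tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

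The samples, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Ppara, then, among genes past the threshold whose 3 values of one genotype all lay above those of the other, the 10 with the largest difference in each direction, leaving out gene models and families of noncoding RNA, olfactory and vomeronasal genes. It took up to 4 members per list, those past the threshold first and then those with the smallest p. The alternatives were a trended and robust prior, 3 other normalizations, 2 filters on dim genes, the mean of all probe sets, all rows of the table, array weights, the replicate number as a block, each array left out in turn, other thresholds and other set tests. The fit without the 2 arrays with the highest negative-control signal, and the fit with that signal as a covariate, were added after the data were seen.

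The fit was tested on simulated data for this comparison, with the gene means and spreads of the 6 arrays, 30746 genes and 200 changed genes in each of 10 simulations. Of genes changed by a log2 difference of 0.5 it called 4.78%, of those changed by 1 it called 80.15% and of those changed by 2 it called 99.39%, with 0.02% of the unchanged genes called. The monocyte and macrophage list, with every member lowered by 0.5, was called in 10 of 10 simulations and 0 of 270 other lists were. The real list had a median difference of -0.27 with members in both directions. The simulation therefore does not show how often a shift like the real one is found. The simulated genes varied independently, whereas genes within the real lists had estimated correlations of up to 0.63, and the 9 other splits of the 6 arrays into 3 and 3 called 3 to 19 lists, so the simulation does not show how often the preset set test calls a list without a shift in these data.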

Results

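Gene expression was profiled on microarrays in mouse acute myeloid leukemia cells driven by MLL-AF9, a fusion oncogene delivered by a retrovirus that also carries green fluorescent protein (GFP). The leukemias had been made in marrow cells with an intact or a disrupted Ppara gene, which encodes a nuclear receptor that senses fatty acids and controls their oxidation. Total RNA came from GFP-positive cells sorted from the bone marrow of secondary transplant recipients. There were 6 arrays, 3 of Ppara+/+ leukemia and 3 of Ppara-/- leukemia, with 1 comparison between them. It asks which genes differ in leukemia cells that lack PPARA, in particular genes of metabolism, myeloid differentiation and immune recognition.

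The deposited log2 signals ran from 1.67 to 14.42, and the median over the 30746 named genes lay between 5.16 and 5.40 on the 6 arrays. Pairs of arrays correlated across genes with r between 0.9838 and 0.9955, where genes are not independent replicates. The 5222 negative-control probe sets had a median of 4.63 to 4.81 on 4 arrays, of 4.99 on Ppara-/- replicate 2 and of 5.16 on Ppara+/+ replicate 1. Those 2 arrays also had the lowest scores on the first principal component, which held 45.9% of the variance (-41.9 for Ppara+/+ replicate 1 and -11.9 for Ppara-/- replicate 2, against 0.8 to 26.6 for the other 4). The labels do not say whether the replicates were separate animals or separate primary leukemias, so the p-values measure the spread between these 6 samples. The number of arrays limits the precision.

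Ppara itself had a signal of 5.19 ± 0.12 (SD, n = 3) in the Ppara-/- samples and 5.08 ± 0.18 (SD, n = 3) in the Ppara+/+ samples. The log2 difference of 0.11 (SE 0.13) did not pass the test (limma, adjusted p = 0.997; exact permutation test, two-sided p = 0.5, where 0.1 is the smallest this design allows). Both levels were close to the negative-control medians. Which part of the gene the probes match is not known from the files, so this signal does not check the genotype labels.

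In Ppara-/- leukemia 36 of 30746 genes differed, 18 higher and 18 lower. Among the genes that rose were Mecom, a zinc finger transcription factor of hematopoietic stem cells, the chemokine receptor Ccr1, the interleukin Il1f9 and the metallothionein Mt2. Among those that fell were Pbx3, a homeobox partner of HOXA9 and MEIS1, the monocyte lectin Clec4a1, the adhesion molecule Vcam1, carbonic anhydrase Car2 and the retrovirus restriction factor Apobec3. The changes ranged from 0.87 to 2.91 in absolute log2 difference, and in each of the 36 genes the 3 values of one genotype lay above the 3 of the other. That separation was seen in 8.7% of all genes, where chance gives 10% with 3 samples against 3. The test was limma's moderated test with Benjamini-Hochberg adjustment, and 1768 genes (5.75%) had an unadjusted p under 0.05. Leaving out 1 array gave 6 to 36 genes, with 6 without Ppara-/- replicate 1, 11 without Ppara-/- replicate 2, 15 without Ppara-/- replicate 3 and 13 without Ppara+/+ replicate 3. Without Ppara+/+ replicate 1 or 2 the count was 36, of which 26 and 24 were among the 36 of all 6 arrays. Without Ppara+/+ replicate 1 and Ppara-/- replicate 2, the 2 arrays with the highest negative-control signal (a fit chosen after the data were seen), limma called 0 genes at an adjusted p under 0.05 and 2947 at an unadjusted p under 0.05, with 2 residual degrees of freedom; the median absolute log2 difference of the 36 genes, which were chosen on these arrays, was 1.29 (median SE 0.14) with all 6 arrays and 1.29 (median SE 0.12) in that fit.

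Every fold given here is a ratio of array signals, and the ranks are of signals, not of RNA levels. The largest changes are ranked here among the called genes that the naming rule allows, 10 in each direction. Of these 20 genes the mean of the lower group lay under 7.91, the lowest 95th percentile of the negative controls, in all but Tmem181a, and both means did in 14, Mecom, Slc15a2, Car2 and Vcam1 among them. The largest increase in signal was that of Slc15a2, a transporter of small peptides, which rose from 4.23 ± 0.12, under the negative-control median of every array, to 6.68 ± 0.23, a signal ratio of 5.48 (mean ± SD, n = 3; log2 difference 2.45, SE 0.14; limma adjusted p = 0.000643). Il1f9, also known as interleukin-36 gamma, rose 4.68-fold (log2 difference 2.23, SE 0.30; limma adjusted p = 0.0439). Mecom rose 4.59-fold, from 5.29 ± 0.47 to 7.49 ± 0.15 (limma adjusted p = 0.0145). Mtss1, which encodes an actin and membrane binding protein, rose 4.52-fold, from 6.18 ± 0.11 to 8.36 ± 0.15 (limma adjusted p = 0.000643). Ccr1 rose 3.56-fold and Mt2 3.52-fold. The adaptor Grb14 (2.55-fold), the protease Asprv1 (2.47-fold), the heat shock protein Hspa2 (2.43-fold) and the membrane protein Tmem181a (2.30-fold) completed the 10 largest increases. In 17 other fits, with other processing or with arrays left out, Il1f9 passed 6 times, Ccr1, Grb14 and Tmem181a 7 times and Mecom 10 times.

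Among the genes that the naming rule allows, the largest decrease in signal was that of Car2, which fell 7.50-fold from 7.86 ± 0.52 to 4.95 ± 0.16 (mean ± SD, n = 3; log2 difference -2.91, SE 0.23; limma adjusted p = 0.00547). Clec4a1 fell 4.23-fold, from 7.18 ± 0.40 to 5.10 ± 0.12 (limma adjusted p = 0.0101). Btla, an inhibitory receptor of lymphocytes, fell 3.27-fold (log2 difference -1.71, SE 0.23). Pbx3 fell 3.18-fold, from 7.95 ± 0.19 to 6.28 ± 0.08 (limma adjusted p = 0.00438). The meiotic cohesin subunit Stag3 fell 3.11-fold, the Ly49 family receptor Klra2 2.85-fold, and Ticam2, an adaptor of Toll-like receptor signalling, 2.84-fold. Vcam1 fell 2.61-fold, Apobec3 2.47-fold and the germ cell gene Tex14 2.31-fold. In the 17 other fits Btla passed 6 times, Vcam1 7 times and Stag3 and Ticam2 8 times, and in the 16 that held them Klra2 passed 7 times and Tex14 9 times.

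**Figure D1:**
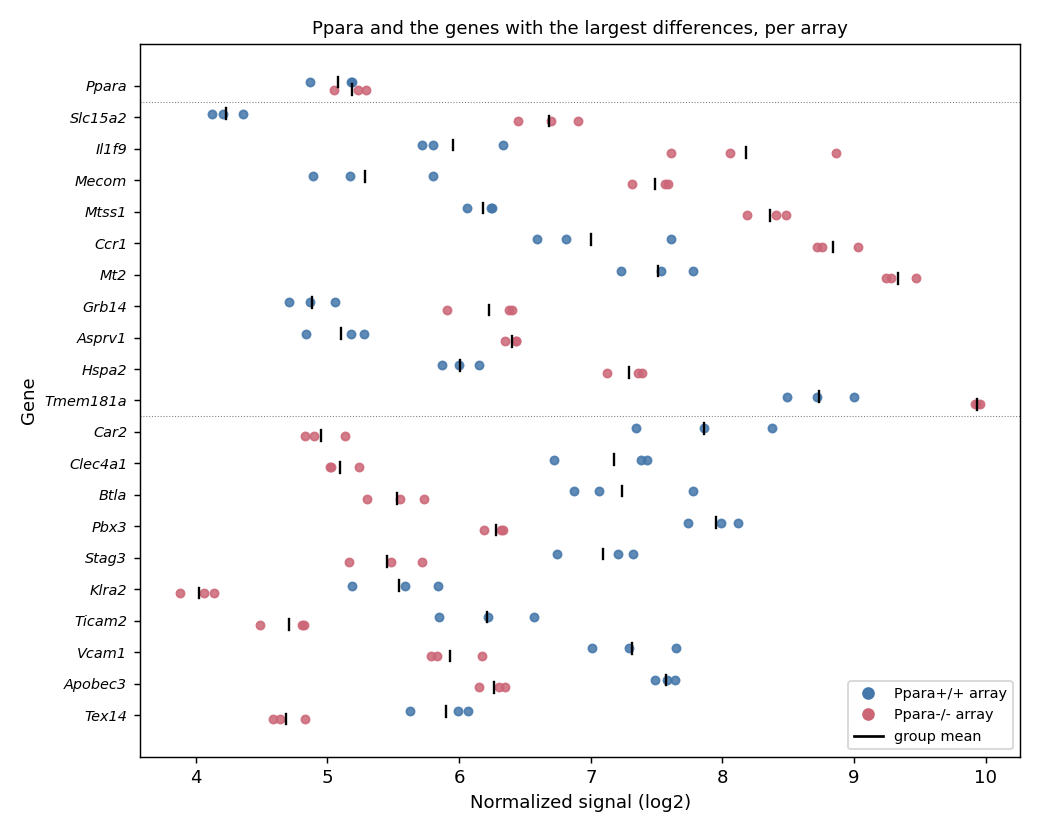
Normalized log2 signal (horizontal axis) of Ppara and of the 10 genes with the largest increase and the 10 with the largest decrease among the called genes that the naming rule allows (vertical axis), with 1 point per array, coloured by genotype, and a bar at each group mean (n = 3). The points of the 2 genotypes do not overlap in any of the 20 genes, while those of Ppara do, with group means of 5.19 and 5.08.

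Genes of monocytes and macrophages were called lower as a group in Ppara-/- leukemia by the set test (limma's camera with a preset correlation between genes, adjusted p = 7.62e-17). With an estimated correlation the call was lost (adjusted p = 0.319, unadjusted p = 0.00996), and limma's fry did not call it (adjusted p = 0.342). Of 59 measured members, 5 of which another list also holds, 44 had a negative and 15 a positive difference, with a median log2 difference of -0.27 (1.21-fold). Over all genes tested 2 members passed, Clec4a1 and Vcam1, both lower (in 13 and 7 of the 17 other fits), and 57 did not pass; adjusted over the list alone, 20 were lower and 1 was higher. Cd68, a lysosomal glycoprotein of macrophages, was at 8.98 ± 0.19 against 9.70 ± 0.14 and the lysosomal protease Ctss at 7.93 ± 0.52 against 9.32 ± 0.27 (adjusted p = 0.138 and 0.139 over all genes; mean ± SD, n = 3, limma). Csf1r, the receptor for the growth factor M-CSF, and the matrix protein Fn1, both singled out after their values were seen, had log2 differences of -0.94 (adjusted p = 0.364) and -2.02 (adjusted p = 0.269). The list mean of every Ppara-/- array lay below that of every Ppara+/+ array (6.98 ± 0.11 against 7.38 ± 0.12; exact permutation test, two-sided p = 0.1, the smallest possible). Without Ppara+/+ replicate 3 the median was -0.15, and with each of the other arrays left out it lay between -0.22 and -0.37.

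The list of immune regulatory ligands and enzymes had 28 negative and 15 positive differences among 43 measured members, with a median of only -0.05. Siglece, an inhibitory sialic acid receptor of myeloid cells, was the 1 member that passed over all genes, lower by 2.08-fold (9.03 ± 0.09 to 7.97 ± 0.15; limma adjusted p = 0.0195), and adjusted over the list alone 3 were lower. The inhibitory receptor Lilrb4a was at 9.41 ± 0.27 against 10.63 ± 0.29 and the cytokine Tgfb1 at 9.92 ± 0.03 against 10.38 ± 0.09 (adjusted p = 0.0709 and 0.214, n = 3, limma). The preset set test called the list lower (adjusted p = 0.000206; adjusted p = 0.462 with an estimated correlation). The list means did not overlap between genotypes (6.35 ± 0.03 against 6.48 ± 0.07, n = 3; exact permutation p = 0.1). The median was -0.11 without Ppara+/+ replicate 1, -0.08 without Ppara-/- replicate 1 and -0.02 without Ppara-/- replicate 2.

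The MLL-AF9 leukemia programme, the genes around HOXA and MEIS1 that the fusion drives, had 18 positive and 7 negative differences among 25 measured members, with a median of 0.23 (1.18-fold). It held 1 gene that rose, Mecom, and 1 that fell, Pbx3; adjusted over the list alone 6 were higher and 2 lower. Hoxa3 was at 7.85 ± 0.10 against 7.09 ± 0.38 and Hoxa4 at 7.26 ± 0.22 against 6.74 ± 0.08 (adjusted p = 0.272 and 0.308 over all genes, n = 3, limma). Hoxa9 and Hoxa7 were not measured by a probe set of their own. The preset set test called the list higher (camera, adjusted p = 0.0188), and with an estimated correlation it did not pass (adjusted p = 0.462). The estimated correlation of this list was 0.01, as preset, yet camera's unadjusted p went from 0.00293 to 0.0434. That change therefore does not come from genes that vary together. The list means did not overlap (8.04 ± 0.03 against 7.84 ± 0.11, n = 3, exact permutation p = 0.1). The call was lost when Ppara+/+ replicate 2, Ppara+/+ replicate 3 or Ppara-/- replicate 2 was left out, with adjusted p = 0.196, 0.133 and 0.275 in the preset test and medians of 0.18, 0.13 and 0.13.

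Cell cycle and oxidative phosphorylation genes also passed the preset set test as lower in Ppara-/- cells, by small amounts. The adjusted p of the preset test was 5.12e-07 for the cell cycle and 6.95e-05 for oxidative phosphorylation, and with an estimated correlation both calls were lost (adjusted p = 0.966 for both). Of 58 cell cycle genes 52 had a negative difference (median -0.15, 1.11-fold), and of 57 oxidative phosphorylation genes 42 did (median -0.12, 1.08-fold). No member of either list passed, over all genes or adjusted over the list alone; at an unadjusted p under 0.05 in limma stood, among others, the cell cycle regulator E2f2 (7.76 ± 0.04 against 8.15 ± 0.20) and the respiratory chain subunit Sdha (7.35 ± 0.26 against 7.77 ± 0.29). The list means of the genotypes overlapped (exact permutation p = 0.4 and 0.2). Without Ppara-/- replicate 3 the medians were -0.04 and -0.05 and both calls were lost (adjusted p = 0.205 and 0.0778), and without Ppara+/+ replicate 1 the cell cycle median was -0.05 (adjusted p = 0.269). Without Ppara-/- replicate 2 the cell cycle median was -0.33.

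**Figure D2:**
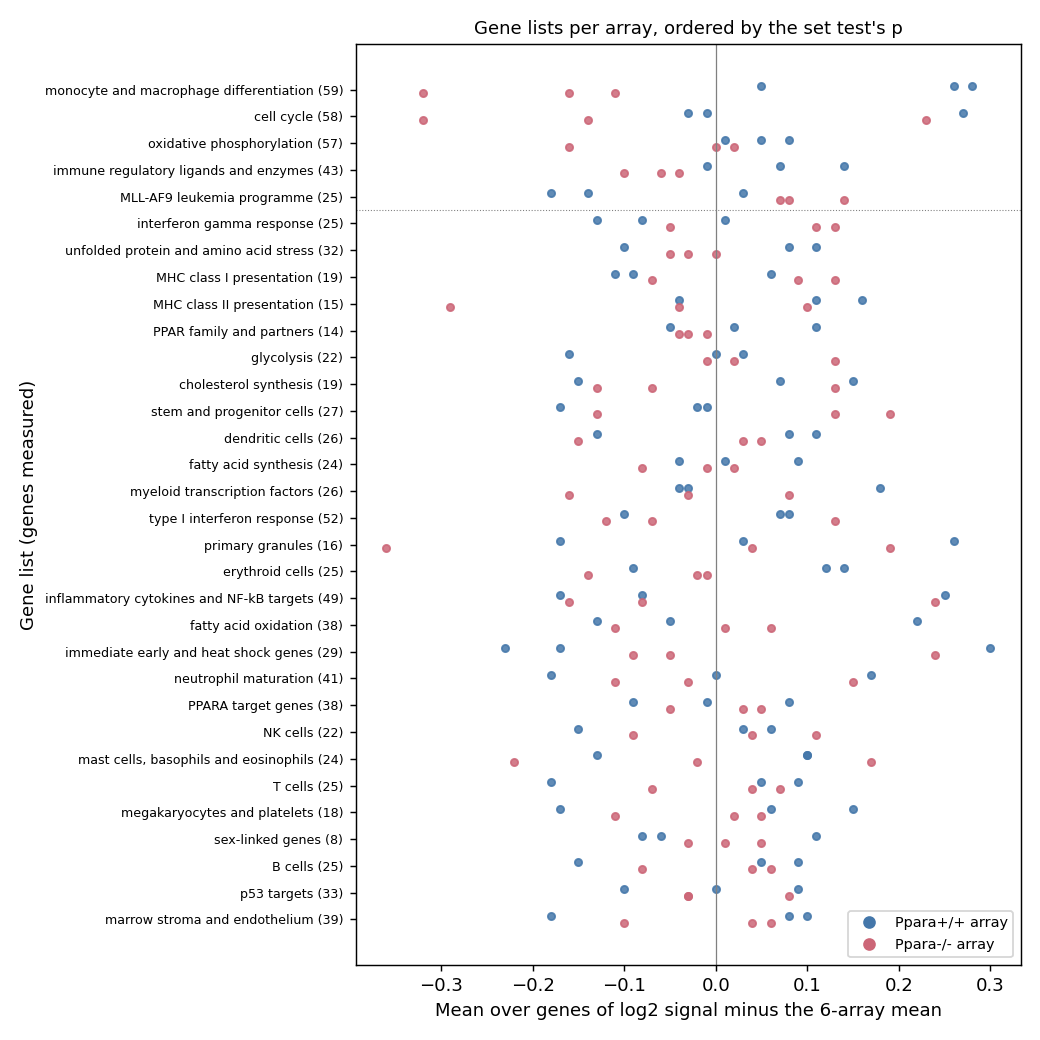
Mean over the genes of each list of the log2 signal minus the gene's mean over the 6 arrays (horizontal axis), with 1 point per array, coloured by genotype, for the 32 gene lists (vertical axis, number of genes measured in parentheses). The lists are ordered by the p of the preset set test, and the 5 above the dotted line passed it; the monocyte and macrophage points of the genotypes do not overlap, with a mean difference of -0.40, while those of the cell cycle do.

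Of the 32 lists tested 5 passed the preset set test, 1 higher and 4 lower, and 27 did not. With 1 array left out 6 to 12 passed, with 5 higher and 7 lower without Ppara+/+ replicate 1. Without Ppara+/+ replicate 2 it was 0 higher and 10 lower. With an estimated correlation limma's camera called 0 lists (3 at an unadjusted p under 0.05) and limma's fry called 0 (2 at an unadjusted p under 0.05). Each array's mean over a list gave, over all 32 lists, exact permutation p-values that were 0.914 or higher after Benjamini-Hochberg adjustment. Since no such p can be under 0.1 before adjustment, a value under 0.05 was out of reach, and this does not count against the lists.

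No list of lipid metabolism passed. The PPARA target genes had a median log2 difference of 0.04 over 38 members, fatty acid oxidation 0.02 over 38, fatty acid synthesis -0.01 over 24, cholesterol synthesis -0.05 over 19 and PPAR family members and partners -0.02 over 14, and none of their members passed over all genes. The mean signal of the PPARA target list was 5.79 ± 0.06 in Ppara-/- and 5.77 ± 0.09 in Ppara+/+ samples (SD, n = 3). Both lay under 7.91, the lowest 95th percentile of the negative controls, so a fall in dim members could be missed. The lipoprotein lipase Lpl, a PPARA target, was at 5.01 ± 0.16 against 6.06 ± 0.28 (n = 3; limma adjusted p = 0.0709 over all genes and 0.00418 adjusted over the list alone), and the PPARA target Angptl4 at 6.27 ± 0.12 against 5.92 ± 0.05 (adjusted p = 0.494). Glycolysis genes had a median of 0.06 over 22 members, with the myeloid hexokinase Hk3 at 10.44 ± 0.04 against 9.92 ± 0.11 (limma adjusted p = 0.178, and 0.016 adjusted over the list alone).

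Other lists of differentiation did not pass either. Neutrophil maturation genes had a median of 0.02 over 41 members and went both ways: adjusted over the list alone 4 were higher, Retnlg and Ncf4 among them, and 8 lower, Stfa2l1 and Stfa3 among them. Primary granule genes had a median of -0.02 over 16 members; adjusted over the list alone Nkg7 was higher and Cst7 and Ctsc were lower. Myeloid transcription factors had a median of -0.04 over 26 members, with Gfi1 at 8.92 ± 0.10 against 8.42 ± 0.06 and Irf5 at 6.95 ± 0.46 against 7.86 ± 0.22 (limma adjusted p = 0.198 and 0.308); adjusted over the list alone, Gfi1 was higher and Irf5 lower. Stem and progenitor genes had a median of 0.05 over 27 members, where Mecom was the 1 member past the threshold, over all genes and adjusted over the list alone.

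Among the lists of immune recognition, MHC class I genes had a median of 0.05 over 19 members (preset adjusted p = 0.069), with H2-Q4, H2-K1 and H2-Q10 higher when adjusted over the list alone (log2 differences of 0.61, 0.42 and 0.37). These values are uncertain, since class I genes are near-identical copies and a probe can match several. MHC class II genes had a median of 0.02 and a mean of -0.16 over 15 members; adjusted over the list alone 3 were lower, Ctss, Ifi30 and H2-DMa, which serve antigen processing and are shared in part with the monocyte list. The interferon gamma list had a median of 0.08 over 25 members (preset adjusted p = 0.069) and the type I interferon list 0.00 over 52, with Oas2 higher and 4 members, Ifi204, Ifi211 and Slfn1 among them, lower when adjusted over the list alone. Inflammatory cytokines and NF-kB targets had a median of 0.03 over 49 members, and Ccl6, a chemokine of myeloid cells, fell 1.99-fold (limma adjusted p = 0.0375; past the threshold in 7 of the 17 other fits); adjusted over the list alone Ccl2 was lower too (log2 difference -0.96). The p53 target list (median 0.04 over 33 members) and the list of unfolded protein and amino acid stress (median -0.09 over 32; preset adjusted p = 0.069) did not pass, and neither they nor the interferon gamma list had a member past the threshold adjusted over the list alone.

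Markers of other cells that the sort could have carried did not pass as lists. Medians were 0.03 for T cells (25 genes), 0.03 for NK cells (22), 0.03 for B cells (25), 0.05 for megakaryocytes and platelets (18), 0.06 for mast cells, basophils and eosinophils (24), -0.02 for dendritic cells (26), 0.04 for marrow stroma and endothelium (39) and 0.01 for erythroid cells (25), a list that holds Car2 and had a mean of -0.11. Adjusted over the list alone Cd209a and Naaa of dendritic cells, Il6ra and Siglecf of the mast cell list, Rgs18 and Itgb3 of megakaryocytes, and Pdgfrb and Eng of stroma and endothelium were lower, and no marker of T, NK or B cells passed. The mean signals of these marker lists ran from 3.91 (NK cells) to 5.62 (megakaryocytes) in Ppara-/- and from 3.87 to 5.65 in Ppara+/+ samples. All lay under 7.91, the lowest 95th percentile of the negative controls, so a difference in carried cells could be missed. Immediate early and heat shock genes, which respond to handling, had a median of 0.03 over 29 members, with Dusp2 higher when adjusted over the list alone. For MHC class II, erythroid, mast, megakaryocyte, fatty acid oxidation, B cell, stroma, neutrophil and cytokine genes the median was above 0 while the set test's direction was lower. Sex-linked genes did not differ by the test (median 0.06 over 8 members): Xist was at 3.60 ± 0.05 against 3.69 ± 0.08 and the Y-linked Eif2s3y at 6.54 ± 0.18 against 6.60 ± 0.41 (mean ± SD, n = 3).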

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

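The fit of all rows of the table was planned, and the probe sets below were singled out after their values were seen. In that fit 6 of the 34737 probe sets not paired with exactly 1 gene differed between the genotypes (limma), 1 higher and 5 lower in Ppara-/- cells, and 0 of the control probe sets did. The higher one was TC1500001586.mm.1, at 6.89 against 5.12 (log2 difference 1.78, SE 0.13; adjusted p = 0.0298); its identifier follows that of the probe set of Mtss1, TC1500001585.mm.1, which was higher by 2.18. The lower ones with the smallest p were TC1000000229.mm.1, at 5.57 against 8.98 (log2 difference -3.41, SE 0.21; adjusted p = 0.0161), and TC1300001895.mm.1, at 5.12 against 6.79 (log2 difference -1.66, SE 0.11; adjusted p = 0.0161). The tables used here do not pair these 3 with a gene.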

How the results depend on the processing

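The fits without the 2 arrays with the highest negative-control signal and with that signal as a covariate were chosen after the data were seen. Ppara, the named genes and the set test directions of the 5 lists past the threshold did not turn under the alternatives; for the called genes this was fixed where arrays were left out, since their groups do not overlap, and the other 27 lists were followed singly only without the 2 arrays, where the mean differences of 5 turned sign: neutrophil maturation from 0.01 to -0.16, fatty acid oxidation from -0.03 to 0.03, type I interferon from -0.04 to 0.04, T cells from 0.03 to -0.01 and B cells from 0.01 to -0.02. The balance of the counts moved: the called list members were 1 higher and 6 lower with all 6 arrays, but 5 higher and 4 lower without Ppara+/+ replicate 1, and the genes 12 higher and 24 lower without Ppara+/+ replicate 2. Against 36 genes, a trended and robust prior called 69, array weights 277 and the upper 70% of genes by signal 57. Normalizing by quantiles again called 22 (9 higher, 13 lower), cyclic loess 14 (5 higher, 9 lower) and centring on the median 12, where the fit as deposited called 18 higher and 18 lower. An adjusted p under 0.10 called 74, limma's treat against a 1.2-fold difference 10 and a fit of all rows 12, 6 of them probe sets of the 36 genes. Without the 2 arrays limma called 0 genes (2947 at an unadjusted p under 0.05) and 0 list members, and with the covariate 30 genes, 21 of them among the 36. Against 7 called list members, the trended prior gave 12, array weights 45, centring 2 and cyclic loess 3. Against 5 lists, array weights gave 10, camera with an estimated correlation 0 (3 at an unadjusted p under 0.05) and fry 0 (2 at an unadjusted p under 0.05). The cause was not tested for these, except that the fit without the 2 arrays has fewer samples, with 2 residual degrees of freedom and a median absolute log2 difference of the 36 genes of 1.29, as with all 6 arrays.

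Leaving out 1 array gave 6 to 36 genes, 6 to 12 lists, 2 to 10 list members and a Ppara difference of 0.00 to 0.18. The 36 genes without Ppara+/+ replicate 1 shared 26 with those of all 6 arrays, and the 36 without Ppara+/+ replicate 2 shared 24. Lists numbered 12 without Ppara+/+ replicate 1, 10 without Ppara+/+ replicate 2 or Ppara-/- replicate 2, and 8 without Ppara-/- replicate 3. Genes numbered 6, 11 and 15 without Ppara-/- replicates 1, 2 and 3 and 13 without Ppara+/+ replicate 3, and list members 2, 4, 3 and 4. Over all alternatives, values of single named genes left the called side 140 times and joined it 40 times. Slc15a2, Mtss1, Car2, Pbx3 and Apobec3 passed in 16 of 17 fits, the exception being that without the 2 arrays, while Il1f9 and Btla passed in 6 of 17, Ccr1, Grb14, Tmem181a, Vcam1 and Ccl6 in 7 of 17, Klra2 in 7 of 16, and Stag3 and Ticam2 in 8 of 17. The MLL-AF9 list was also lost with centring (adjusted p = 0.0517) and in camera on ranks (adjusted p = 0.0635). With the replicate number as a block the fit called 12 genes and 6 lists. Deviations of samples with the same number correlated at -0.33, -0.47 and 0.11, and no sample correlated best with its own number. These values show no pairing by number but cannot exclude one, since deviations within a group of 3 are not independent. Ppara, Klra2 and Tex14 have no value among genes at or above the median gene, since that filter removes them. Genes near the negative controls limit what the arrays resolve.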

Other observations

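The tests below of the negative-control arrays, the macrophage markers, single arrays and the percent of linked genes were chosen after the patterns were seen. The fits with 1 array left out were planned, and only their use as a test of a pattern was chosen then. The values of the splits at an unadjusted p and those of the monocyte and cell cycle lists in each split were also chosen after the patterns were seen. So were the splits with an estimated correlation and the place of Mtss1. The test of the neutrophil list was chosen after its own value was seen. The macrophage markers were picked after Vcam1, and the percent of linked genes after Apobec3, had been seen among the called genes. Genes outside the naming rule also passed, and these are singled out after their values were seen. In Ppara-/- cells the membrane protein gene Mctp2 was higher (log2 difference 1.10), as were the phosphatase Ptpn3 (1.11) and Cables1 (0.94), and the zinc finger gene Zfp182 (-1.18) and Fgfbp3 (-1.18) were lower (limma adjusted p = 0.0193, 0.0439, 0.0457, 0.035 and 0.0457).

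The 36 genes that differed between the genotypes were weighed first. With 10 splits of the 6 arrays the share of splits as large cannot be under 0.05; 1 split, the real one, called 36 genes and the highest other called 0 (limma), but at an unadjusted p under 0.05 the real split had 1768 genes and the highest other 4541, and the 4 of 9 others above the real one were those with the 2 arrays of highest negative-control signal on one side, which points to a structure of the samples. Passenger alleles, left around the targeted gene from the strain in which it was made, may change neighbouring genes. Within 20 Mb of Ppara 1 of 689 genes was called, Apobec3 (5.8 Mb away), and 1 of 337 on the rest of that chromosome, Mtss1 (26.8 Mb away), against 34 of 29404 on other chromosomes (odds ratio within 20 Mb 1.26, 95% interval 0.0308 to 7.51; Fisher's exact p = 0.556), and 7.11% of the genes within 20 Mb had an unadjusted p under 0.05 against a median of 5.59% in windows of as many neighbouring genes, 7 of 43 windows being as high. These leave open linked alleles for Apobec3 and Mtss1, the loss of PPARA, and differences between the primary leukemias, which were not tested.

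The lower monocyte and macrophage list was weighed next: in 9 of the 10 splits at least as many lists passed as the 5 of the real split, with 19 in the highest other, and a share under 0.05 cannot be had; with an estimated correlation the real split called 0 and the highest other 1, and correlated genes within lists were not separated from a structure of the samples as the source of these counts. For this list itself the absolute median was 0.27 in the real split and at most 0.18 in the others, and the log10 of camera's p -17.6 against -10.9 or higher (p = 0.00996 against 0.0584 or higher with an estimated correlation). This list had the smallest p of the real split, so the comparison favours that split. The absolute median of the cell cycle list reached 0.33 in other splits. The 2 arrays with the highest negative-control signal as the whole cause stay open. Without them the median was -0.22 and the mean difference -0.30 (SE 0.11, on 2 residual degrees of freedom). The sign of that mean difference was fixed, since the list means of the genotypes do not overlap. With so few arrays its size cannot decide the question. Fewer host macrophages in the sort, which GFP gating should remove, may contribute: 17 macrophage markers of the list had a median 0.05 above that of the other 42 members (bootstrap SE 0.18; one-sided permutation p = 0.583), and 11 of the 17 were lower, 4 of them at an unadjusted p under 0.05 (Vcam1 -1.39, Adgre1 -0.66, Msr1 -0.57 and Gpnmb -0.49 in log2 difference), and 6 higher, 0 of them at that p (limma), with the levels of C1qa at 5.56 against 5.67 and of Apoe at 7.64 against 8.03, which leaves this open. A turn from monocyte to neutrophil genes stays open, the neutrophil list differing by 0.01 (SE 0.13) over the 6 arrays with members that go both ways. Without the 2 arrays the neutrophil list differed by -0.16 (SE 0.09), which cannot decide this on 2 residual degrees of freedom. A direct effect of the genotype is open too.

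The lower cell cycle and oxidative phosphorylation lists were weighed last. A single array may account for them: without Ppara-/- replicate 3 the cell cycle median went from -0.15 to -0.04 and that of oxidative phosphorylation from -0.12 to -0.05. The 2 arrays with the highest negative-control signal stay open. Without them the medians were -0.21 for the cell cycle and -0.10 for oxidative phosphorylation, sizes that go against the explanation. Both preset calls held (camera, adjusted p = 5.23e-13 and 0.00157). These calls cannot weigh either way, since the test presets a correlation of 0.01 where 0.63 and 0.21 were estimated. The mean differences were -0.20 (SE 0.09) and -0.10 (SE 0.09), the latter within its spread. With that signal as a covariate the medians were -0.04 and -0.07 (camera, adjusted p = 0.252 and 0.00872), which ended the cell cycle call. Relative to the 6-array mean, the cell cycle list was highest on those 2 arrays, 0.27 on Ppara+/+ replicate 1 and 0.23 on Ppara-/- replicate 2. The other arrays lay between -0.32 and -0.01. In the 4 splits with both on one side the list's absolute median was 0.33, 0.33, 0.24 and 0.13, against 0.15 in the real split. An effect of the genotype on these lists cannot be told apart from a single array or from these 2 arrays.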
